A study of Mus musculus with 15 samples.

How the data were processed

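Total RNA of mouse embryonic stem (ES) cells was measured on 15 single-colour Affymetrix whole-transcript arrays, 3 in each of 5 groups. The cells were of a single line that had been adapted to culture with a pair of kinase inhibitors (2i) and that carries a biotin and FLAG tag knocked into Ctnnb1, the gene of beta-catenin, together with the biotin ligase BirA. Per the labels' protocols, CHIR99021 was used at 3 µM and PD0325901 at 1 µM, factors were withdrawn for 24 h before RNA extraction, RNA was isolated with TRIZOL and purified on RNeasy columns, and it was labelled with the whole-transcript kits. The array values were deposited by the authors as log2 values summarised per probe set with RMA (background correction, quantile normalization and a summary over the probes of a set), per the submitters' processing notes. The RMA version is not given in the sources used here. Quantile normalization gives the arrays nearly the same distribution, so a change shared by most genes would not be seen in these values, and RMA values compress fold changes of weakly expressed genes.

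The table held 34760 probe sets with values from 3.74 to 13.99, and the array medians lay between 6.98 and 7.06. All value columns matched a sample, and 0 columns were left unused. Gene names came from the platform annotation given with the table, which listed 22961 of the probe sets: 21640 had exactly 1 gene symbol, 1321 had several, and 11799 are unnamed here. Of the 21640, 21553 had a gene identifier that was found in the RefSeq gene table, which was used for names alone. The genome build of the array annotation is not given in the sources used here, so no coordinates are printed. Probe sets with several symbols named no gene. Where a gene had more than 1 probe set (954 genes), the set with the highest mean over the 15 arrays stood for it, which left 19937 genes. Of 345 entries in the gene lists, 322 were measured, and the others are not reported here. No filter on level was applied, and no detection calls were used here, so a low value may be background.

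Samples were grouped by their labels. A linear model with the 5 groups and no intercept was fitted to all 15 arrays with limma 3.58.1 (lmFit and eBayes, default settings) in R 4.3.3. The 7 comparisons were CHIR minus DMSO, PD03 minus DMSO, 2i minus DMSO, 2i minus CHIR, 2i minus PD03, the interaction of the inhibitors, defined as (2i minus PD03) minus (CHIR minus DMSO), and 2iLIF minus 2i. A gene passed when its Benjamini-Hochberg adjusted p over all genes of a comparison was under 0.05, with no minimum fold. All adjusted p-values of genes are from limma, two-sided. The fit had 10 residual degrees of freedom and 5.09 prior degrees of freedom. The number of arrays, 3 per group, limits the precision: the median standard error of a difference between groups was 0.0509 on the log2 scale, and 0.072 for the interaction. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

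Fixed before the data were examined, 22 gene lists were tested with camera of limma with a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. They covered Wnt/beta-catenin targets, ERK response and feedback genes, LIF/STAT3 targets, naive pluripotency, general pluripotency, formative and primed epiblast, primitive streak and mesoderm, extra-embryonic endoderm, neural progenitors, trophoblast, fibroblast and feeder cells, germ line genes, 2-cell-stage genes, DNA methylation machinery, p53 targets, integrated stress response, cholesterol synthesis, glycolysis, ribosome biogenesis, cell cycle, Nodal and BMP response, and epithelial junction and mesenchymal genes. Some genes stand on more than 1 list. Camera passed 44 of the 154 tests, and 14 of these also passed with the correlation estimated from the data. For each list the number of members past the threshold is given over all genes tested, and also adjusted over the list alone. Named genes followed a rule fixed before the data were examined. For each comparison it took the 6 genes with the highest and the 6 with the lowest log2 fold change among genes past the threshold whose arrays did not overlap between the groups (no such condition for the interaction; chance gives no overlap for 10% of genes with 3 arrays against 3), leaving out symbols of predicted genes. It added up to 4 members of each list past the threshold with the largest absolute change. A short list was taken whatever its result (measured members: Ctnnb1, Axin2, Dusp6, Socs3, Nanog, Esrrb, Klf2, Klf4, Tfcp2l1, Pou5f1, Sox2, Fgf5, Otx2). The text leaves out some genes that the rule gives, and some results of the short list, among them those of Esrrb. Correlations of log2 fold changes are across genes, which are not independent replicates.

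The procedure was tested on simulated data with the real genes' means and spreads. Simulated errors were independent between genes and arrays, so the rates do not cover deviations that genes share on the real arrays. For CHIR minus DMSO with 19937 genes and 50 changed genes per size, 86% of genes changed by 0.3, 98% of those changed by 0.5 and 100% of those changed by 1 or by 2 on the log2 scale were recovered, and 5 unchanged genes passed. Arrays of a group were compared before averaging: the standard deviation of the difference between 2 arrays of a group ran from 0.0792 to 0.127, and no pair was identical. Alternatives fixed before the data were examined were a low-value filter, a 2-fold minimum, the mean of a gene's probe sets, a further quantile normalization, median centring, a variance trend with robust eBayes, array weights, a fit to the compared groups alone, the replicate number as a block, leaving out each replicate in turn, and for the lists an estimated correlation. A covariate for a shared deviation of the arrays was added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.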

Results

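The series profiled gene expression in 2i-adapted mouse ES cells as the components of their medium were withdrawn. CHIR99021 inhibits the kinase GSK3, which marks beta-catenin for degradation. PD0325901 inhibits MEK, the kinase that activates ERK. LIF is a cytokine that activates STAT3. The 2iLIF group (n = 3) stayed in long-term culture with both inhibitors and LIF. The other groups, each with n = 3, spent the last 24 h without LIF: the 2i group kept both inhibitors, the CHIR group kept CHIR99021, the PD03 group kept PD0325901, and the DMSO group kept neither. The design asks how the transcriptome responds to GSK3 inhibition, to MEK inhibition and to both together. Values are log2 RMA signals on 15 arrays, with 19937 genes tested. Words such as rose, raised, fell and lowered describe the first group of a comparison against the second, not a change over time.

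One known target of each pathway, Axin2, Dusp6 and Socs3, differed between the groups with and without the factor that acts on that pathway. Axin2, a feedback target of Wnt/beta-catenin signalling, had a mean of 9.31 ± 0.06 (SD, n = 3) in CHIR and 9.19 ± 0.05 (n = 3) in 2i, against 7.66 ± 0.05 (n = 3) in PD03 and 7.86 ± 0.23 (n = 3) in DMSO. Dusp6, a phosphatase of ERK that ERK signalling induces, was at 11.06 ± 0.04 in DMSO and 10.41 ± 0.03 in CHIR, and at 9.34 ± 0.06 in PD03 and 9.29 ± 0.06 in 2i (SD, n = 3 each). Socs3, a feedback target of STAT3, stood 1.64 ± 0.08 (SE) higher in 2iLIF than in 2i, and its means lay between 7.36 and 7.77 in the groups without LIF. Means of the core pluripotency gene Pou5f1 (Oct4) lay between 12.49 and 12.54 in the 5 groups and did not pass in any of the 7 comparisons. Sox2 ranged from 11.41 to 11.57 and passed in PD03 minus DMSO alone (0.16 ± 0.04 SE, limma adjusted p = 0.0185), a call that was lost without PD03 replicate 1 and without DMSO replicate 2 or 3. The mRNA of Ctnnb1 itself ranged from 11.91 to 12.03 and passed in 2i minus PD03 alone (-0.12 ± 0.03, adjusted p = 0.0152). That call was lost without 2i replicate 2 or 3 and without PD03 replicate 2. Arrays with CHIR99021 nevertheless all read lower for Ctnnb1 (11.885 to 11.948) than arrays without it (11.986 to 12.053). The difference was small, at -0.09 ± 0.03 in CHIR minus DMSO and in 2i minus DMSO (limma adjusted p = 0.0683 and 0.0591).

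**Figure D1:**
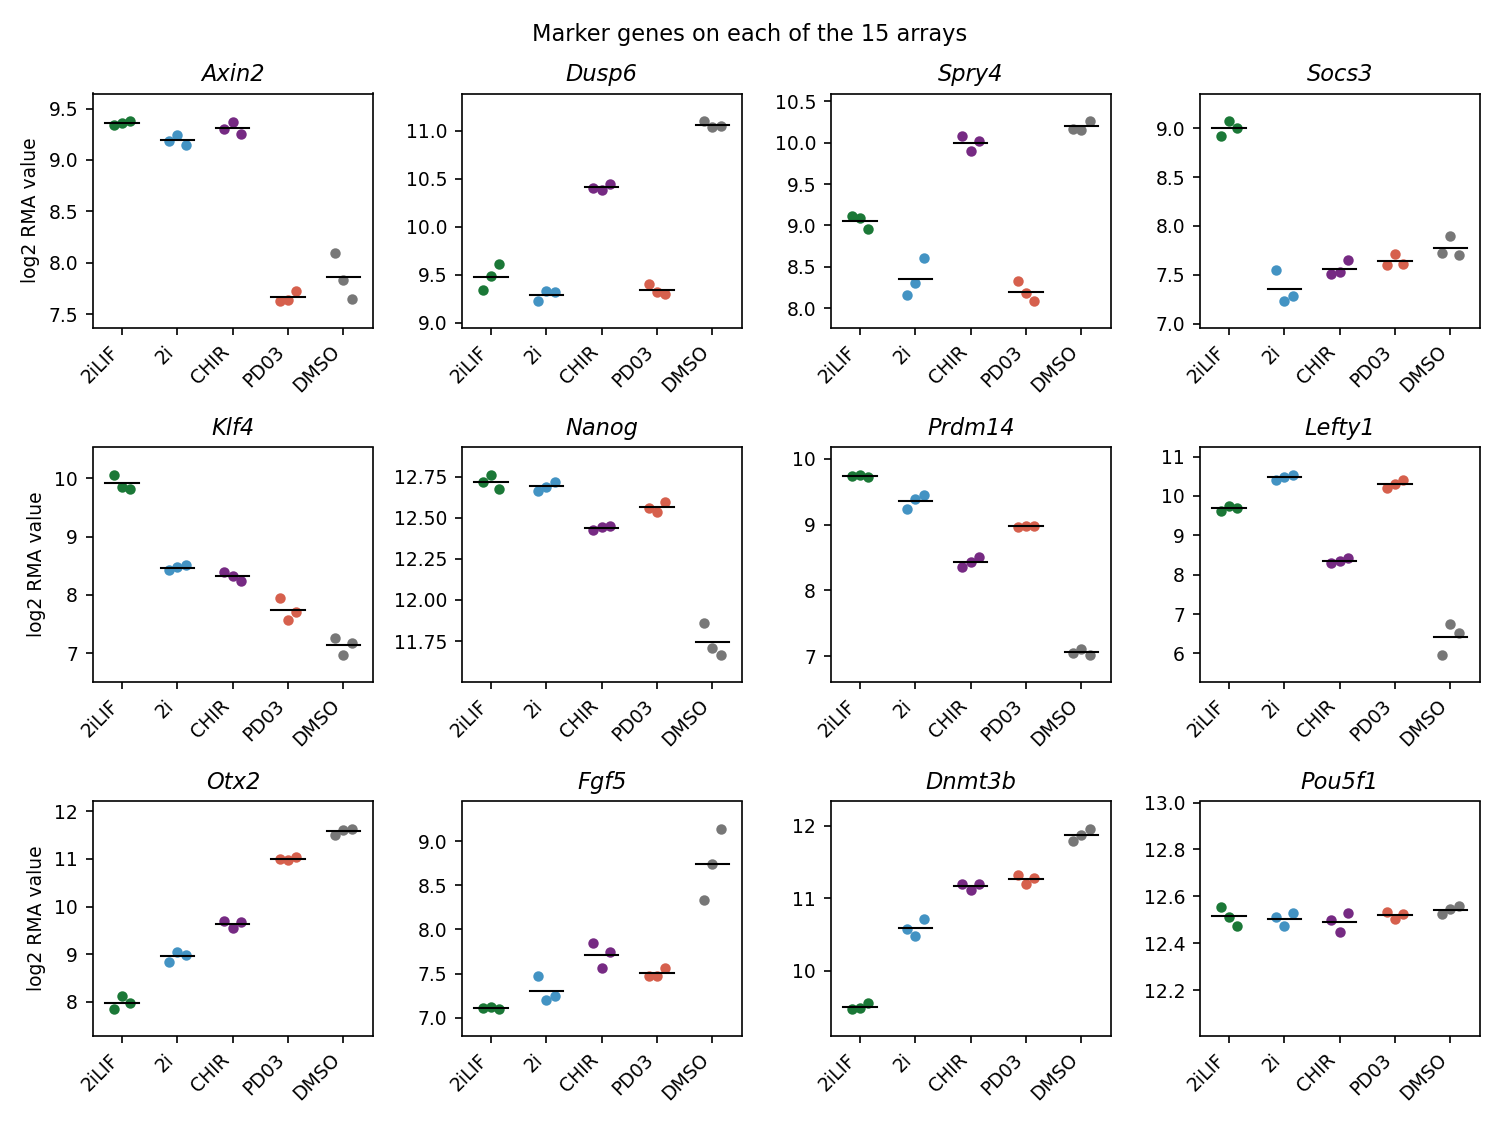
Log2 RMA values of 12 genes on each of the 15 arrays (points; 3 per group), with the group mean as a line and a separate vertical scale per gene. Axin2 is high where CHIR99021 is present, Dusp6 is lowest where PD0325901 is present, Socs3 stands apart in 2iLIF, and the means of Pou5f1 lie between 12.49 and 12.54.

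The first comparison asks how cells kept in CHIR99021 alone differ from cells after withdrawal of all factors. In CHIR minus DMSO the largest increases were in Gmnc, a coiled-coil protein of the geminin family (3.75 ± 0.08 SE, 13.4-fold), Pglyrp1, a peptidoglycan recognition protein (3.57 ± 0.10, 11.9-fold), and Nt5e, an ecto-nucleotidase (2.88 ± 0.08, 7.37-fold). Plagl1, Rasgrp1 and Btla followed, at 2.71, 2.47 and 2.44. The CHIR means of Gmnc (9.19), Nt5e (9.74) and Btla (8.14) were above those in 2iLIF (6.65, 7.56 and 6.41). They were also above those in 2i (7.55, 8.03 and 6.65). Pglyrp1, Plagl1 and Rasgrp1 had means of 10.54, 9.74 and 9.57 in CHIR and of 10.29, 10.63 and 9.50 in 2iLIF. The largest decreases were in Tmem154 (-2.17 ± 0.08), Otx2, a homeobox factor of the postimplantation epiblast (-1.94 ± 0.07), the ephrin ligand Efnb2 (-1.68 ± 0.09) and the endocytic receptor Lrp2 (-1.67 ± 0.05). Each of these genes had no overlap between the 3 CHIR and the 3 DMSO arrays, which the naming rule required. The highest adjusted p among them was 2.42e-09 (limma). The other probe set of Tmem154 gave -1.02. The DMSO means of Gmnc (5.44) and Btla (5.70) and the CHIR mean of Tmem154 (5.98) were below 6, near background, so their folds are lower bounds if these values are background.

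Of 18 measured Wnt/beta-catenin targets, 8 were higher with CHIR99021 and 3 lower (8 and 4 adjusted over the list alone), with a median of 0.086. Tnfrsf19 was at 1.70 ± 0.04, Axin2 at 1.45 ± 0.08 and Sp5 at 0.54 ± 0.07. Sp8, whose DMSO mean of 5.86 was near background, was at 0.50 ± 0.06. The list passed with the preset correlation (camera adjusted p = 0.00616). The adjusted p was 0.325 with an estimated correlation, and Lef1, Myc and Nkd1 of this list fell. Of 16 naive pluripotency genes, 14 rose and 2, Fgf4 and Gbx2, fell (14 and 2 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 2.12e-14, and 0.0128 with an estimated correlation). Among them Prdm14, a repressor of DNA methyltransferase genes, rose by 1.38 ± 0.05, Tbx3 by 1.32 ± 0.07, Tcl1 by 1.19 ± 0.07, Klf4 by 1.19 ± 0.09, Klf2 by 0.96 ± 0.04 and Nanog by 0.70 ± 0.04. Means in 2iLIF, CHIR and DMSO were 12.72, 12.44 and 11.74 for Nanog and 12.08, 11.04 and 10.02 for Tfcp2l1. For such genes the difference is a smaller deficit against 2iLIF in CHIR than in DMSO. Of the 14 higher members, Nr0b1, Nr5a2 and Dppa3 were not lower in CHIR than in 2iLIF. Formative and primed epiblast genes fell in 13 of 17 cases and rose in 2, Cdh2 and Wnt8a (14 and 2 adjusted over the list alone), with Grhl2 at -1.20 ± 0.09, Fgf5 at -1.02 ± 0.14 and the de novo DNA methyltransferase Dnmt3a at -0.89 ± 0.05 (camera adjusted p = 1.42e-09). For this list the adjusted p was 0.0576 with an estimated correlation. Lower members mostly stood above 2iLIF in both groups: means in 2iLIF, CHIR and DMSO were 7.98, 9.64 and 11.58 for Otx2. Foxd3 differed, at 7.38, 7.26 and 7.94.

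Nodal and BMP response genes were higher in 6 of 12 cases and lower in 2 (7 and 2 adjusted over the list alone; camera adjusted p = 1.66e-04, and 0.0411 with an estimated correlation). Lefty2 and Lefty1, secreted Nodal antagonists, rose by 2.00 ± 0.07 and 1.95 ± 0.13, and Nodal rose by 1.27 ± 0.04, while Id2, an inhibitor of helix-loop-helix factors, was at -0.90 ± 0.10. The DMSO mean of Lefty2 was 5.56, also near background, so its folds over DMSO in CHIR, PD03 and 2i are lower bounds in the same sense. Of 14 cholesterol synthesis genes, 12 fell and none rose (12 and 0 adjusted over the list alone), with a median of -0.21 and with Lss and Hmgcs1, enzymes of the pathway, at -0.36 ± 0.06 and -0.34 ± 0.04 (camera adjusted p = 9.88e-08, and adjusted p = 0.0723 with an estimated correlation). Members of the DNA methylation machinery were lower in 5 of 10 cases and higher in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0171, and adjusted p = 0.325 with an estimated correlation). The lower ones were Dnmt3a, Dnmt3b, Dnmt3l and the 5-methylcytosine oxidases Tet1 and Tet3. Ribosome biogenesis genes were higher in 5 of 18 cases (5 adjusted over the list alone), led by Rrs1 at 0.33 ± 0.06 (camera adjusted p = 0.00616). That list had an adjusted p of 0.459 with an estimated correlation, and 0.0857 without DMSO replicate 1.

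In all, 4144 genes passed in CHIR minus DMSO, 1998 higher and 2146 lower. Most changes were small: with a 2-fold minimum the count was 92, of which 68 were higher. The 2 ERK phosphatase genes Dusp4 and Dusp6 were also lower in CHIR than in DMSO, by -0.84 ± 0.06 and -0.65 ± 0.06, but the ERK list as a whole did not pass (2 members higher and 7 lower of 21, camera adjusted p = 0.148).

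The next comparison asks the same of PD0325901. In PD03 minus DMSO the largest increases were in Lefty1 (3.90 ± 0.13 SE, 14.9-fold) and Lefty2 (2.90 ± 0.07, 7.46-fold). Anxa2, a membrane-binding annexin, and Mme, the peptidase neprilysin, each rose by 2.05 (± 0.12 and ± 0.11), and the transporters Slco4c1 and Slc15a1 rose by 2.00 ± 0.12 and 1.95 ± 0.13. The largest decreases were in the ERK target genes Dusp4 (-2.17 ± 0.06), Etv4 (-2.09 ± 0.08), Dusp6 (-1.72 ± 0.06) and Spry4 (3.99-fold lower). Sema6a, a semaphorin, and the connexin gene Gja1 followed at -1.67 ± 0.15 and -1.64 ± 0.07. The highest adjusted p among these genes was 1.21e-06 (limma), and their arrays did not overlap between the groups, as the naming rule required.

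ERK response and feedback genes fell in 13 of 21 cases and rose in 1, Epha4 (14 and 3 adjusted over the list alone; camera adjusted p = 1.77e-10, and 0.00671 with an estimated correlation). Naive pluripotency genes rose in 14 of 16 cases and fell in 1, Gbx2 (15 and 1 adjusted over the list alone; median 0.57; camera adjusted p = 6.2e-16, and 0.00671 with an estimated correlation). Prdm14 rose by 1.92 ± 0.05, Tcl1 by 1.41 ± 0.07, Klf2 by 1.20 ± 0.04 and Nanog by 0.82 ± 0.04. Formative and primed epiblast genes fell in 12 of 17 cases and none rose (13 adjusted over the list alone; camera adjusted p = 7.83e-13, and 0.0233 with an estimated correlation). The kinase gene Pim2 was at -1.63 ± 0.13, Grhl2 at -1.31 ± 0.09, Fgf5 at -1.23 ± 0.14 and Otx2 at -0.58 ± 0.07.

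Nodal and BMP response genes were higher in 5 of 12 cases and lower in 1, Id3 (5 and 1 adjusted over the list alone; camera adjusted p = 2.41e-04, and 0.0252 with an estimated correlation), and here Id2 rose by 0.82 ± 0.10. Neural progenitor genes were higher in 5 of 13 cases (5 higher and 1 lower adjusted over the list alone): the adhesion molecule Ncam1 rose by 1.83 ± 0.04, the neuronal tubulin Tubb3 by 0.86 ± 0.07, Nes by 0.64 ± 0.07 and Pax6 by 0.43 ± 0.05 (camera adjusted p = 0.0137). The adjusted p for that list was 0.284 with an estimated correlation. Ribosome biogenesis genes were lower in 6 of 18 cases (10 adjusted over the list alone), including Rrp9 at -0.28 ± 0.06 (camera adjusted p = 5.88e-05, and adjusted p = 0.284 with an estimated correlation). The germ line genes Piwil2 (-0.49 ± 0.05), Mael (-0.48 ± 0.10) and Hormad1 (-0.24 ± 0.05) were lower among 15 measured (3 adjusted over the list alone; camera adjusted p = 7.81e-04, and adjusted p = 0.109 with an estimated correlation). Extra-embryonic endoderm genes were higher in 4 of 16 cases and lower in 1 (4 and 1 adjusted over the list alone), with the laminin gene Lama1 at 0.57 ± 0.05 and Sparc at 0.45 ± 0.04 (camera adjusted p = 0.0421). That call had an adjusted p of 0.571 with an estimated correlation, and was also lost without PD03 replicate 2 (0.118), without DMSO replicate 1 (0.0824) and without DMSO replicate 3 (0.0775).

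In PD03 minus DMSO 3354 genes passed, 1729 higher and 1625 lower, and 76 with a 2-fold minimum, 48 of them higher. Axin2 was at -0.20 ± 0.08 (adjusted p = 0.11), and the Wnt/beta-catenin list did not pass (1 higher and 5 lower of 18, camera adjusted p = 0.132).

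Both inhibitors together were compared with their joint absence. In 2i minus DMSO Lefty1 rose by 4.06 ± 0.13 SE (16.7-fold), Lefty2 by 3.95 ± 0.07 (15.4-fold), Pglyrp1 by 3.67 ± 0.10 (12.7-fold), Plagl1 by 3.15 ± 0.10 and the ETS factor Spic by 2.92 ± 0.10. Otx2 was at -2.63 ± 0.07, which is 6.19-fold lower, Lrp2 at -2.41 ± 0.05, Foxi3 at -2.29 ± 0.10, Dusp4 at -2.14 ± 0.06 and Myrf at -2.12 ± 0.10. The highest adjusted p among these genes was 2.2e-10 (limma), with no overlap of arrays, as the naming rule required. The DMSO means of Lefty2 (5.56) and Spic (5.34) were near background, so their folds are lower bounds if these values are background. Naive pluripotency genes rose in 14 of 16 cases and 2, Fgf4 and Gbx2, fell (14 and 2 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 2.8e-12, and 0.00948 with an estimated correlation). Prdm14 rose by 2.30 ± 0.05, and Klf4 by 1.33 ± 0.09.

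Formative and primed epiblast genes fell in 14 of 17 cases and none rose (14 adjusted over the list alone), with a median of -0.82 (camera adjusted p = 2.11e-16, and 0.00948 with an estimated correlation). The de novo methyltransferase genes Dnmt3a, Dnmt3b and Dnmt3l were at -1.38 ± 0.05, -1.29 ± 0.06 and -0.85 ± 0.06. The DNA methylation list, which holds them, had 4 members lower and 2, Prdm14 and Tet2, higher of 10 (5 and 2 adjusted over the list alone; camera adjusted p = 0.0119, and adjusted p = 0.199 with an estimated correlation), and its adjusted p was 0.0513 with the low-value filter. ERK response and feedback genes were lower in 14 of 21 cases and higher in 2 (14 and 2 adjusted over the list alone; camera adjusted p = 5.15e-09, and 0.00948 with an estimated correlation). Of 12 general pluripotency genes 5 were lower and 1 higher (5 and 1 adjusted over the list alone), with Utf1 at -0.73 ± 0.04 and the RNA-binding protein gene Lin28a at -0.69 ± 0.06 (camera adjusted p = 0.00624, and adjusted p = 0.14 with an estimated correlation).

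Cholesterol synthesis genes fell in 10 of 14 cases (10 adjusted over the list alone; median -0.19; camera adjusted p = 2.78e-06, and adjusted p = 0.105 with an estimated correlation). Nodal and BMP response genes were higher in 5 of 12 cases and lower in 2 (6 and 2 adjusted over the list alone), with Nodal at 1.59 ± 0.04 and Id2 at -0.65 ± 0.10 (camera adjusted p = 0.00624, and adjusted p = 0.105 with an estimated correlation). Germ line genes were lower in 4 of 15 cases and higher in 1, Dazl (8 and 1 adjusted over the list alone), with Mael at -1.01 ± 0.10 (camera adjusted p = 0.00624). The germ line call had an adjusted p of 0.149 with an estimated correlation and of 0.0861 with the low-value filter. The Wnt/beta-catenin list did not pass in 2i minus DMSO (7 higher and 4 lower of 18, camera adjusted p = 0.154), although Axin2 rose by 1.33 ± 0.08. Of all genes 5088 passed, 2713 higher and 2375 lower, and 180 with a 2-fold minimum, 100 of them higher.

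**Figure D2:**
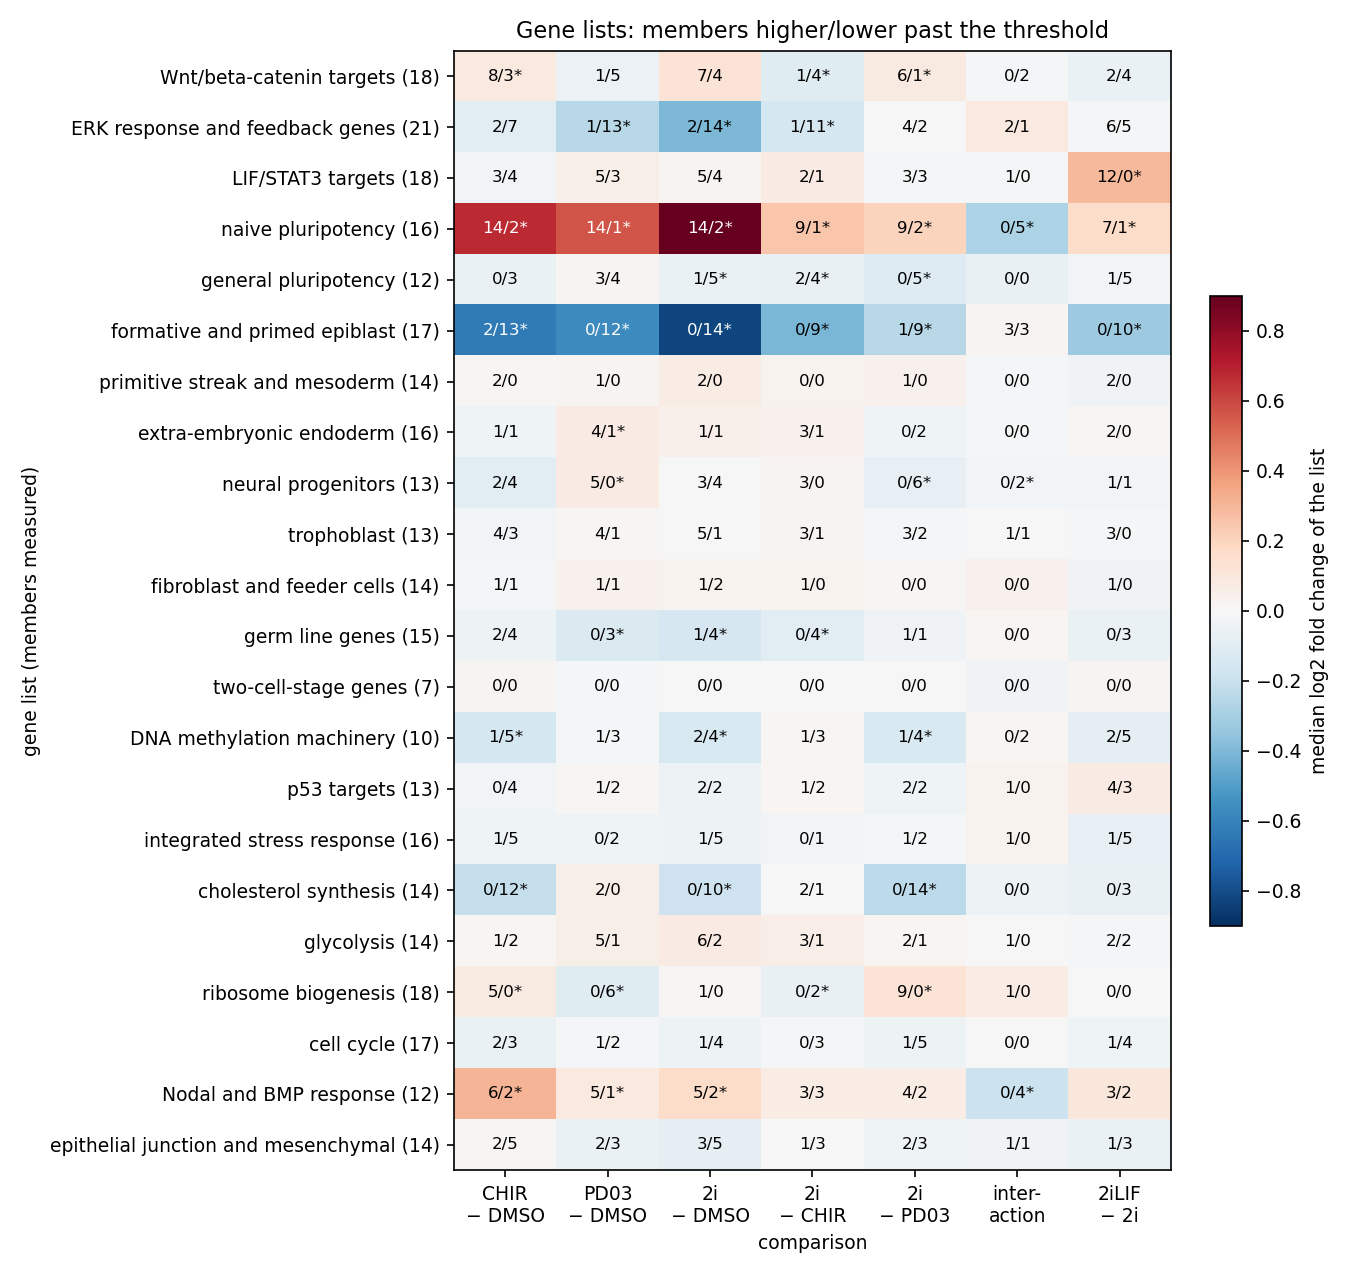
Median log2 fold change (colour) of each of 22 gene lists (rows, with the number of members measured) in 7 comparisons (columns), where each cell gives the members higher and lower past the threshold of 0.05 and an asterisk marks a camera adjusted p under 0.05. Naive pluripotency genes have a median of 0.91 in 2i minus DMSO, and cholesterol synthesis genes are lower in 14 of 14 cases in 2i minus PD03.

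The effect of PD0325901 was then taken in the presence of CHIR99021. In 2i minus CHIR the ERK targets Etv4, Spry4, Dusp4 and Dusp6 were at -1.79 ± 0.08, -1.64 ± 0.09, -1.30 ± 0.06 and -1.12 ± 0.06, and the ERK list had 11 members lower and 1 higher of 21 (12 and 1 adjusted over the list alone; camera adjusted p = 2.11e-14, and 0.00356 with an estimated correlation). Lefty1 rose by 2.11 ± 0.13 (4.33-fold), Lefty2 by 1.95 ± 0.07, Rasgef1a by 1.44 ± 0.04 and the creatine kinase gene Ckb by 1.23 ± 0.04. The integrin gene Itga1 was the lowest at -1.87 ± 0.10, and Nt5e (-1.71 ± 0.08) and Gmnc (-1.64 ± 0.08), which CHIR99021 alone had raised, were lower with both inhibitors than with CHIR99021 alone. Formative and primed epiblast genes fell in 9 of 17 cases (10 adjusted over the list alone; camera adjusted p = 1.65e-16, and 0.0139 with an estimated correlation), with Lef1 at -1.12 ± 0.05 and Wnt8a at -0.71 ± 0.04.

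Naive pluripotency genes were higher in 9 of 16 cases and lower in 1, Gbx2 (10 and 1 adjusted over the list alone), with Prdm14 at 0.92 ± 0.05 (camera adjusted p = 4.13e-06, and adjusted p = 0.0706 with an estimated correlation). Wnt/beta-catenin targets had 4 members lower, Lef1, Myc, Sp5 and Tnfrsf19, and 1 higher of 18 (5 and 2 adjusted over the list alone; camera adjusted p = 0.00183, and adjusted p = 0.227 with an estimated correlation). Axin2 was at -0.12 ± 0.08 (adjusted p = 0.42). Germ line genes had 4 of 15 lower (4 adjusted over the list alone; camera adjusted p = 1.22e-04, and adjusted p = 0.0706 with an estimated correlation). General pluripotency genes had 4 lower and 2 higher of 12 (5 and 2 adjusted over the list alone; camera adjusted p = 0.0157, and adjusted p = 0.227 with an estimated correlation), a call with an adjusted p of 0.073 with the low-value filter. Ribosome biogenesis genes had 2 of 18 lower (3 adjusted over the list alone; camera adjusted p = 9.25e-04, and adjusted p = 0.4 with an estimated correlation). In all 1887 genes passed, 1137 higher and 750 lower, and 30 with a 2-fold minimum.

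The effect of CHIR99021 in the presence of PD0325901 is given by 2i minus PD03. Pglyrp1 rose by 3.00 ± 0.10 SE (8.0-fold), Plagl1 by 2.54 ± 0.10, Gmnc by 2.19 ± 0.08, Spic by 2.13 ± 0.10 and the cathepsin gene Ctsc by 2.11 ± 0.07. Otx2 was at -2.05 ± 0.07, Efnb2 at -1.77 ± 0.09, the small GTPase gene Rhob at -1.56 ± 0.07, Lrp2 at -1.51 ± 0.05 and Id2 at -1.47 ± 0.10. The PD03 mean of Gmnc was 5.36, near background. Cholesterol synthesis genes fell in 14 of 14 cases (14 adjusted over the list alone), with a median of -0.24 and with Hmgcs1 at -0.47 ± 0.04 and Lss at -0.39 ± 0.06 (camera adjusted p = 1.36e-10). The adjusted p for that list was 0.0802 with an estimated correlation. In PD03 minus DMSO the list had 2 members higher and none lower.

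Wnt/beta-catenin targets were higher in 6 of 18 cases and lower in 1, Lef1 (7 and 1 adjusted over the list alone), with Axin2 at 1.53 ± 0.08 and Tnfrsf19 at 1.41 ± 0.04 (camera adjusted p = 0.014, and adjusted p = 0.273 with an estimated correlation). Neural progenitor genes were lower in 6 of 13 cases (6 adjusted over the list alone), with Pax6 at -1.12 ± 0.05, Nes at -0.56 ± 0.07 and Ncam1 at -0.54 ± 0.04 (camera adjusted p = 2.73e-04, and adjusted p = 0.131 with an estimated correlation). Ribosome biogenesis genes were higher in 9 of 18 cases (9 adjusted over the list alone), with Wdr12 at 0.29 ± 0.04 and Nip7 at 0.27 ± 0.05 (camera adjusted p = 1.06e-04, and adjusted p = 0.261 with an estimated correlation). Naive pluripotency genes were higher in 9 of 16 cases and lower in 2 (11 and 2 adjusted over the list alone), with Tbx3 at 1.11 ± 0.07, Tfcp2l1 at 0.80 ± 0.05 and Klf4 at 0.72 ± 0.09 (camera adjusted p = 1.7e-04, and adjusted p = 0.131 with an estimated correlation). Nanog was at 0.13 ± 0.04 (adjusted p = 0.0623).

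Formative and primed epiblast genes were lower in 9 of 17 cases and higher in 1, Cdh2 (9 and 2 adjusted over the list alone; camera adjusted p = 1.59e-08, and adjusted p = 0.0802 with an estimated correlation). General pluripotency genes were lower in 5 of 12 cases (8 adjusted over the list alone), among them Tcf7l1, a repressor of Wnt targets, at -0.47 ± 0.04 (camera adjusted p = 1.7e-04, and adjusted p = 0.0802 with an estimated correlation). The DNA methylation machinery had 4 members lower and 1 higher of 10 (5 and 1 adjusted over the list alone; camera adjusted p = 0.00308, and adjusted p = 0.181 with an estimated correlation). In 2i minus PD03 3891 genes passed, 2008 higher and 1883 lower, and 63 with a 2-fold minimum. Dusp6 was at -0.04 ± 0.06 (adjusted p = 0.69).

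**Figure D3:**
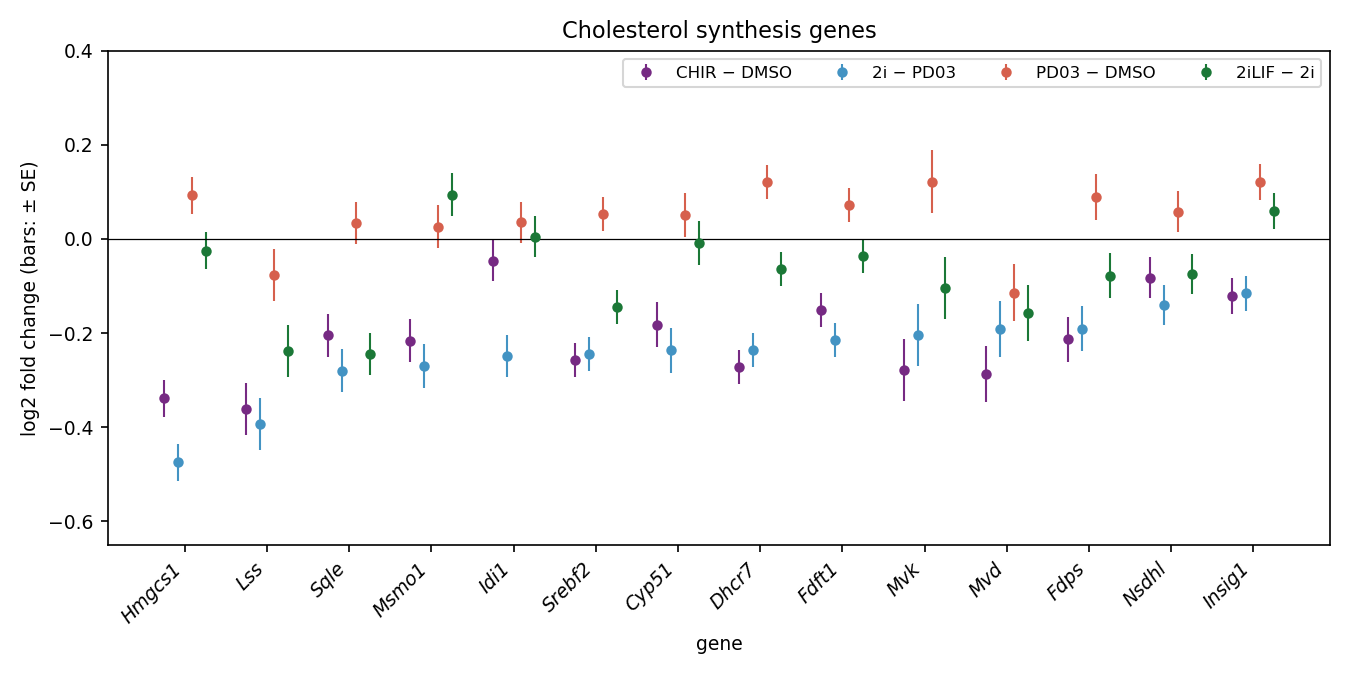
Log2 fold change (points) with its SE (bars) of the 14 cholesterol synthesis genes measured, in 4 comparisons, ordered by 2i minus PD03. All 14 points of 2i minus PD03 and of CHIR minus DMSO lie below 0, and 2 genes in PD03 minus DMSO passed the threshold above 0.

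Changes due to an inhibitor were set against each other with and without the other inhibitor. Across 19937 genes, CHIR minus DMSO and 2i minus PD03, which share no arrays, had a correlation of log2 fold changes of r = 0.777 (rho = 0.602) and a slope of 0.701. Of the genes that passed in both, 1160 were higher in both (201.2 expected for independent lists), 1243 lower in both (202.7 expected) and 34 opposite. For PD0325901, PD03 minus DMSO against 2i minus CHIR gave r = 0.732 (rho = 0.544) and a slope of 0.541. Here 825 genes were higher in both (98.6 expected), 536 lower in both (61.1 expected) and 10 opposite. Error in the changes with a single inhibitor lowers both slopes, so they do not by themselves measure a weaker response beside the other inhibitor. The effects of the single inhibitors against the shared DMSO arrays had r = 0.328. Unchanged groups simulated against shared controls gave r = 0.499, and the covariance was 0.0114 against a simulated 0.00182, a difference of 0.00958. Of the genes past the threshold with both single inhibitors, 592 were higher in both (173.3 expected), 673 lower in both (174.9 expected) and 433 opposite (349 expected). The 3 DMSO arrays cannot be split with 2 in each part, so part of the excess over independent lists may come from the shared controls.

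The interaction tests whether the 2i response differs from the sum of the single responses on the log2 scale. Klf2 rose by 0.96 with CHIR99021 alone and 1.20 with PD0325901 alone but by 1.31 with both, an interaction of -0.85 ± 0.05 SE (limma adjusted p = 8.46e-07). Prdm14 had an interaction of -0.99 ± 0.07, Tcl1 of -0.69 ± 0.10 and Nanog of -0.57 ± 0.06. Of 16 naive pluripotency genes, 5 had a negative interaction past the threshold and none a positive interaction (11 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 1.52e-18, and 0.00243 with an estimated correlation). Nodal and BMP response genes had 4 of 12 negative (5 adjusted over the list alone), with Lefty1 at -1.79 ± 0.18, Lefty2 at -0.95 ± 0.10 and Nodal at -0.82 ± 0.06 (camera adjusted p = 2.18e-10, and 0.00243 with an estimated correlation). Neural progenitor genes had 2 of 13 negative, Ncam1 and Pax6 (3 adjusted over the list alone; camera adjusted p = 0.0153). The neural call had an adjusted p of 0.517 with an estimated correlation and of 0.106 without 2i replicate 2.

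Genes that CHIR99021 alone raised and that stayed lower with both inhibitors gave other strong negative values: Gmnc at -1.56 ± 0.11, the immune receptor gene Btla at -1.54 ± 0.11 and Nt5e at -1.36 ± 0.11. The neurofilament gene Nefm was at -1.29 ± 0.10. The PD03 and DMSO means of Gmnc (5.36 and 5.44), Btla (5.75 and 5.70) and Nefm (5.91 in both) and the DMSO mean of Lefty2 (5.56) were near background, so the sizes and the order of their interactions are uncertain. High positive interactions were in Wt1, a zinc-finger factor (1.17 ± 0.15), the receptor gene Lpar6 (0.92 ± 0.10) and Gpm6a (0.89 ± 0.11), and Dusp4 and Dusp6 were at 0.87 ± 0.09 and 0.60 ± 0.08. Axin2 was at 0.08 ± 0.11 (adjusted p = 0.871). In all 406 genes passed, 186 positive and 220 negative. Of these, 122 were higher with each inhibitor alone, and 121 of the 122 had a negative interaction. A further 126 were lower with each inhibitor alone, and 123 of the 126 had a positive interaction. The DMSO arrays enter both single effects and, with the opposite sign, the interaction, so part of this sign pattern follows from shared arrays. The count was 14 with a 2-fold minimum, 269 without PD03 replicate 1, 255 without PD03 replicate 3, and 617 with a covariate for a shared deviation of the arrays, chosen after seeing the data.

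**Figure D4:**
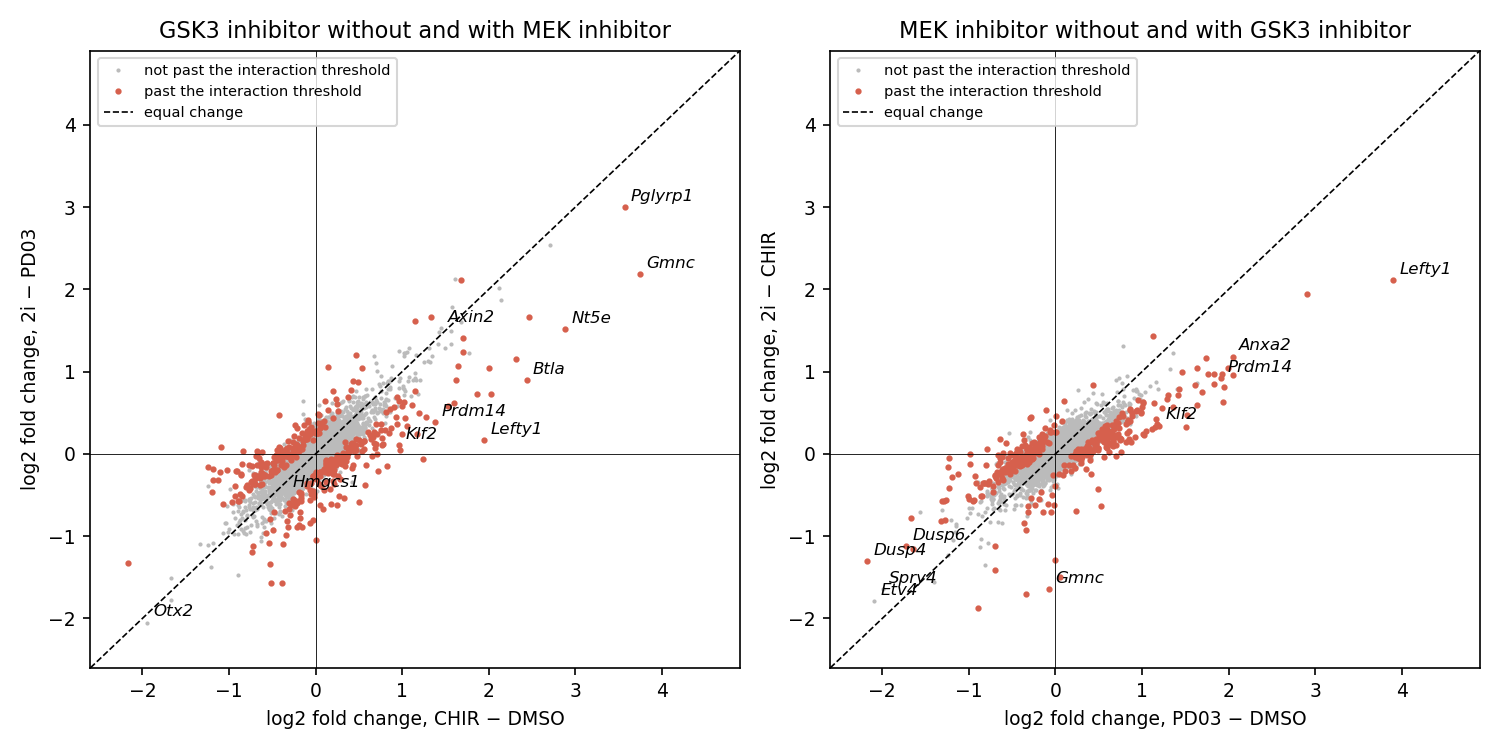
Log2 fold change of each of 19937 genes for 1 inhibitor without the other (horizontal) and with the other (vertical), with CHIR99021 on the left and PD0325901 on the right; red points are the 406 genes past the interaction threshold and the dashed line marks equal change. The slope of the vertical on the horizontal value was 0.701 for CHIR99021 and 0.541 for PD0325901. Error in the horizontal values lowers such slopes, so the gap to equal change is not all a difference in response.

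The last comparison asks what LIF adds when both inhibitors are present. In 2iLIF minus 2i, Bcl3, a member of the IkappaB family, rose by 1.83 ± 0.08 SE (3.55-fold), Socs3 by 1.64 ± 0.08 (3.12-fold), the homeobox gene Hesx1 by 1.52 ± 0.08, Serpinb1a by 1.46 ± 0.09 and Klf4 by 1.45 ± 0.09. Lef1, a nuclear partner of beta-catenin, was at -1.58 ± 0.05, Map7d3 at -1.56 ± 0.12, Enpp3 at -1.39 ± 0.04, Vrtn at -1.28 ± 0.09, Dnmt3l at -1.27 ± 0.06 and the receptor gene Ror1 at -1.27 ± 0.10. The highest adjusted p among these genes was 3.6e-07 (limma), and their arrays did not overlap, as the naming rule required. The other probe set of Socs3 gave 0.01. The 2i means of Hesx1 (5.86) and Serpinb1a (5.68) were near background. LIF/STAT3 targets rose in 12 of 18 cases and none fell (12 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 1.32e-17, and 0.00244 with an estimated correlation).

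Formative and primed epiblast genes fell in 10 of 17 cases (10 adjusted over the list alone), with Dnmt3a at -1.19 ± 0.05, Dnmt3b at -1.08 ± 0.06 and Otx2 at -0.97 ± 0.07 (camera adjusted p = 2.35e-11, and adjusted p = 0.0516 with an estimated correlation). Naive pluripotency genes were higher in 7 of 16 cases and lower in 1, Fgf4 (9 and 1 adjusted over the list alone), with Tfcp2l1 at 0.73 ± 0.05, Tbx3 at 0.66 ± 0.07 and Gbx2 at 0.47 ± 0.07 (camera adjusted p = 4.96e-07, and adjusted p = 0.0567 with an estimated correlation). Of the 7, Gbx2, Klf4, Klf5 and Tfcp2l1 also stand on the LIF/STAT3 list, so the naive call is not independent of the LIF/STAT3 call. The Nodal antagonist genes parted in this comparison, with Lefty2 at 0.36 ± 0.07 and Lefty1 at -0.78 ± 0.13. Nanog and Klf2 differed by 0.03 ± 0.04 (adjusted p = 0.802) and 0.07 ± 0.04 (adjusted p = 0.311). In 2iLIF minus 2i 2437 genes passed, 910 higher and 1527 lower, and 42 with a 2-fold minimum. Across genes, the LIF effect correlated with CHIR minus DMSO at r = 0.243 and with PD03 minus DMSO at r = 0.228, comparisons that share no arrays with it.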

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

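The tests in this part were set out before their results were seen, apart from the look into the highest random assignment. A test of the difference itself, the interaction, picked out results in which the effect of CHIR99021 differed with and without PD0325901: 406 genes, and the naive pluripotency list (median -0.29), the Nodal and BMP response list (median -0.19) and the neural progenitor list (median -0.02). The neural progenitor call rested on 2 of 13 members, and its adjusted p was 0.517 with an estimated correlation and 0.106 without 2i replicate 2. Of the 220 genes with a negative and the 186 with a positive interaction, those that the naming rule picked are given here. The negative ones were Lefty1 (-1.79), Gmnc (-1.56), Btla (-1.54), Nt5e (-1.36), Gprc5a (-1.30), Nefm (-1.29), Prdm14 (-0.99), Lefty2 (-0.95), Ncam1 (-0.86), Klf2 (-0.85), Nodal (-0.82), Tcl1 (-0.69), Wnt8a (-0.66), Nanog (-0.57), Epha4 (-0.47), Lef1 (-0.42), Smad7 (-0.41), Pax6 (-0.40), Dnmt3l (-0.36), Tfap2a (-0.34), Tnfrsf19 (-0.29) and Vim (-0.28). The positive ones were Wt1 (1.17), Il10 (1.08), Lpar6 (0.92), Sema6a (0.89), Gpm6a (0.89), Dusp4 (0.87), Fgf5 (0.82), Grhl2 (0.73), Krt18 (0.70), Dusp6 (0.60), Sall2 (0.59), Sgk1 (0.41), Gadd45a (0.34), Cldn4 (0.33), Slc7a11 (0.33), Rrp9 (0.33) and Pdk1 (0.29). Gmnc, Btla, Nefm, Lefty2 and Il10 had at least 1 group mean below 6, near background, so the sizes of their interactions are uncertain. The calls of Dnmt3l, Fgf5, Gadd45a, Rrp9, Sema6a, Sgk1, Slc7a11 and Tnfrsf19 were lost without at least 1 replicate.

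Of the genes past the interaction threshold, 121 of the 122 that each inhibitor alone raised lay below the sum of the single responses in 2i, and 123 of the 126 that each inhibitor alone lowered lay above it. Saturation of the array is argued against for the raised genes as a whole. Of 213 genes with a negative interaction that were higher with an inhibitor alone, 2.3% (5 genes) had a 2i mean above 12. The median 2i mean of the 213 was 9.16. Saturation stays open for single genes with high means, such as Nanog (12.69 in 2i) and Vim (12.46 in 2i). Background is argued against for the opposite direction as a whole, since 6.1% (11 of 179 genes) had a 2i mean below 6, and their median was 8.59. The cut of 6 lies below the level of the low-value filter (7.01), and genes between these levels were not counted. A floor therefore stays open for single genes with low means, such as Sall2 (6.675 in 2i) and Sema6a (6.61 in PD03). A single deviating DMSO array is argued against for the naive list, whose adjusted p stayed at or below 8.41e-16 without each DMSO array in turn. Error common to all 3 DMSO arrays and any biological explanation were not tested, and both stay open.

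Of 100 assignments of the 12 arrays without LIF to the 4 groups, 2 gave as many genes in the interaction as the real 406, the real one included. Such assignments put the effects of the single inhibitors into the spread within groups, and 96 of the 99 others gave 0, so the share does not decide whether chance can be excluded for the interaction. The highest of the others gave 4090 genes, and the next gave 219. The assignment with 4090 placed all 6 arrays with CHIR99021 on the positive side of the contrast and all 6 without it on the negative side, so it measured the effect of CHIR99021, a structure of the samples. For the other comparisons, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real split alone (1 of the 10) gave 4144 genes in CHIR minus DMSO, 3354 in PD03 minus DMSO, 5088 in 2i minus DMSO, 1887 in 2i minus CHIR, 3891 in 2i minus PD03 and 2437 in 2iLIF minus 2i, and the highest other split gave 0 in each. Every other split mixes arrays of both groups and puts their difference into the spread within groups, so these 0 counts decide nothing.

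The 13120 probe sets that are unnamed here or carry several symbols entered no gene comparison. Fitted on their own with limma, 320 of them passed in CHIR minus DMSO, 267 in PD03 minus DMSO, 592 in 2i minus DMSO, 86 in 2i minus CHIR, 261 in 2i minus PD03, 1 in the interaction and 122 in 2iLIF minus 2i.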

How the results depend on the processing

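The covariate for a shared deviation of the arrays was chosen after seeing the data. Of 515 named-gene results past the threshold, 435 kept their call under every alternative run, 390 of 7919 alternative values lost it, and 0 changed direction. Of 44 list results past the threshold, 14 kept their call throughout, 40 of 722 alternative values lost it, and 30 of the 40 were with an estimated correlation. The 10 others were the extra-embryonic endoderm list in PD03 minus DMSO (5 values, adjusted p 0.0589 with quantile normalization, 0.0703 with array weights, and from 0.0775 to 0.118 without a replicate), and ribosome biogenesis in CHIR minus DMSO (0.0857), germ line (0.0861) and DNA methylation (0.0513) in 2i minus DMSO, general pluripotency in 2i minus CHIR (0.073) and neural progenitors in the interaction (0.106). With a 2-fold minimum, which removes small changes by construction, the counts became 92 (CHIR minus DMSO), 76 (PD03 minus DMSO), 180 (2i minus DMSO), 30 (2i minus CHIR), 63 (2i minus PD03), 14 (interaction) and 42 (2iLIF minus 2i). The covariate and the replicate block cannot move fold changes in this balanced design, so they test the calls alone. The interaction count of 406 became 617 with the covariate, which removes shared residual spread, and ran from 255 (without PD03 replicate 3) to 437 (without DMSO replicate 1) when a replicate was left out, with 269 without PD03 replicate 1. The remaining counts stayed within 1.5 times their value. Directions changed only for genes near 0 that did not pass, and the cause was not tested. Ctnnb1 in 2i minus CHIR went to -0.0218 with median centring, -0.000265 with array weights and from -0.0174 to 0.0141 without a replicate. In 2iLIF minus 2i Ctnnb1 went to 0.00429 with median centring, 0.00857 with array weights and from -0.0166 to 0.015 without a replicate. Pou5f1 went to -0.0104 (median centring) and from -0.0101 to 0.0304 (without a replicate) in 2i minus CHIR, and to -0.00672 (quantile normalization) and from -0.0116 to 0.0301 (without a replicate) in 2iLIF minus 2i. Sox2 in 2i minus CHIR went to -0.0166 with median centring and from -0.0114 to 0.0384 without a replicate. In the interaction Axin2 ran from -0.0425 to 0.181 without a replicate, and Socs3 went to 0.0337 with the mean of its probe sets. The low-value filter moved 2 of the 5 correlations by more than their spread, to 0.813 and 0.789. The groups share replicate numbers, but these did not pair the samples across all groups. Of 30 same-number pairs, 10 had residual correlations over 0.1, with a mean of -0.016. Their values ran from -0.364 to 0.341, and 4 of 15 arrays were closest to an array of their own number. A pairing within part of the groups was not tested. Same-number pairs of 2iLIF with 2i had 0.341, 0.125 and -0.149 for replicates 1, 2 and 3. Those of 2iLIF with CHIR had 0.278, 0.187 and -0.032, and those of 2i with CHIR had 0.063, 0.234 and 0.108. Most of these pairs, picked after their values were seen, were positive, so a pairing within the groups with CHIR99021 stays open. With the replicate block the counts were 4007, 3229, 4944, 1780, 3756, 352 and 2348 in the order above. Signal over background was not given per probe set, so calls at low values are limited by it to an unknown extent.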

Other observations

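The covariate for a shared deviation of the arrays and the test of the replicate number below were chosen after seeing the data. D-type cyclins went separate ways. Ccnd2 rose by 1.77 ± 0.10 (SE, 3.4-fold) in CHIR minus DMSO, was at -0.81 ± 0.10 in PD03 minus DMSO, and was lower with LIF, at -1.14 ± 0.10 in 2iLIF minus 2i, where Ccnd1 was at -0.34 ± 0.06 and Ccnd3 rose by 0.29 ± 0.04. The cell cycle list as a whole did not pass in any comparison (17 measured, lowest camera adjusted p 0.0606). Of 13 trophoblast genes, 5 were higher and 1 lower in 2i minus DMSO (5 and 1 adjusted over the list alone), and the list did not pass there or elsewhere (lowest adjusted p 0.061). The factors Tfap2c and Tead4 rose by 0.99 ± 0.08 and 0.89 ± 0.04 in 2i minus DMSO, and Tfap2c was 0.97 ± 0.08 higher in 2iLIF than in 2i. The keratin genes moved apart in 2i minus DMSO, with Krt18 at -0.77 ± 0.05 and Krt8, chosen after its values were seen, at 0.50 ± 0.07. Among p53 targets the pro-apoptotic gene Pmaip1 was at -1.20 ± 0.08 and Gadd45a at -0.85 ± 0.06 in PD03 minus DMSO, with no call for the list (13 measured, lowest adjusted p 0.061). Btg2 was higher in that comparison, at 0.22 ± 0.05, and the remaining 10 members did not pass.

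Eomes was the leading gene of the primitive streak and mesoderm list, and rose by 0.87 ± 0.10 in 2i minus DMSO and by 0.92 ± 0.10 in 2iLIF minus 2i, while the list did not pass (14 measured, lowest adjusted p 0.336). Epcam, an epithelial adhesion gene, was at -0.69 ± 0.04 and Vim rose by 0.44 ± 0.03 in 2i minus DMSO (epithelial and mesenchymal list, 14 measured, lowest adjusted p 0.0824). Of the 14, 3 were higher and 5 lower there, and the lower ones included Snai2 (-0.42 ± 0.09) and Twist1 (-0.18 ± 0.05). The glucose transporter gene Slc2a3 rose by 0.58 ± 0.05 and Pdk1 was at -0.43 ± 0.04 in 2i minus DMSO (glycolysis list, 14 measured, lowest adjusted p 0.0616). In the integrated stress response list the cystine transporter gene Slc7a11 was at -0.61 ± 0.06 in 2iLIF minus 2i (16 measured, lowest adjusted p 0.061). Fibroblast and feeder genes (14 measured) and 2-cell-stage genes (7 measured) had a lowest adjusted p of 0.494 each.

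Cholesterol synthesis genes were lower in 12 of 14 cases in CHIR minus DMSO and in 14 of 14 in 2i minus PD03, with an adjusted p of 0.0723 and 0.0802 for the list with an estimated correlation. A trend with signal level is argued against in 2i minus PD03, the comparison in which it was tested. There 0% of 10000 random lists matched on mean level had a median as low, the lowest being -0.131. Genes of the random lists were drawn singly, while the list had an estimated inter-gene correlation of 0.233. The share therefore speaks to signal level and is not a measure of chance. With a deviation shared by arrays of different groups as a covariate, the list's median in 2i minus PD03 was -0.237. The covariate's scores sum to 0 in each group, so it cannot move a difference between groups and this value decides nothing. Other lists argue against a shift along that deviation in 2i minus PD03. The cholesterol list had a median loading on it of -0.346, in SD of all loadings. Primitive streak and mesoderm (1.12), extra-embryonic endoderm (1.102) and fibroblast and feeder genes (1.085) had larger loadings. Their median changes were 0.042, -0.041 and 0.011. An effect of GSK3 inhibition on these cholesterol synthesis genes stays open, and no other readout of the pathway was tested.

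Arrays of different groups deviated together from their group means along an axis that held 29.5% of the residual variance, with 2iLIF replicate 1 (0.453) and DMSO replicate 2 (0.403) at one end and DMSO replicate 3 (-0.378) and 2iLIF replicate 3 (-0.302) at the other. Progress along the DMSO minus 2iLIF difference is argued against, since across genes the loadings had r = 0.004 with it. The lists with the highest median loadings, in SD of all loadings, were primitive streak and mesoderm (1.12), extra-embryonic endoderm (1.102) and fibroblast and feeder genes (1.085), against -0.13 for naive pluripotency and -0.044 for formative and primed epiblast. A replicate number acting alike in all groups is argued against too, since same-number pairs had a mean residual correlation of -0.016. A number shared by part of the groups stays open, because single pairs ran from -0.364 to 0.341 and the mean can hide it. A dependence on signal level is consistent with the loadings, which had r = -0.33 with mean level, and may reflect labelling or background differences between arrays. The design gives no biological factor for this axis, and a difference in cells of other lineages between arrays was not tested and stays open.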
